A study of Mus musculus with 12 samples.

How the data were processed

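RNA from 12 samples of mouse CD4+ T cells was hybridised to Affymetrix Mouse Gene ST 1.0 arrays, which measure each transcript with a probe set of short oligonucleotides. The samples form 6 groups of 2 arrays: regulatory T cells (Tregs) from the spleens of mice carrying the wild-type (WT), M354 or M176 form of Foxp3, and conventional CD4+ T cells transduced in culture with a retrovirus encoding WT, M354 or M176 Foxp3. Groups were taken from the sample labels. The amino acid changes that M354 and M176 stand for are not given in the sources used here, and neither are the genome build and the version of the probe set library.

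Per the submitters' processing notes, the authors summarised the arrays with Affymetrix Power Tools by the RMA method, which corrects background, aligns the distributions of the arrays and combines the probes of a set. The values deposited are intensities on a linear scale, 1 per probe set and array, and their distributions are close but not identical between arrays. The table held 20716 probe sets, with a median intensity per array between 101.5 and 117.4. No depth is defined for an array. The number of arrays, 2 per group, limits the precision.

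Probe sets were joined to genes with the annotation supplied for the table. Of the probe sets, 17703 had 1 gene symbol, 1246 had several and 1767 had none. The Entrez numbers of 17635 matched the reference gene table and 0 symbols needed an update. Singly named probe sets gave 16426 genes, and for 734 genes with several probe sets the brightest was used. A gene was tested if it lay above the median (percentile 50) of its own array on at least 2 of the 12 arrays, which left 8918 genes. The table holds few genes of chromosomes 1, 10 and 11, with 29, 15 and 226 named genes, so that Ctla4, Ikzf2, Icos, Il10, Prdm1, Ifng, Il4, Bcl2, Tcf7, Itgae and Top2a are not analysed here. Their absence also shortens the gene lists.

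Intensities were converted to log2 and fitted with limma 3.58.1 in R 4.3.3, with statmod 1.5.0. The model had 1 mean per group, all 12 arrays and no block, which left 6 residual degrees of freedom; the empirical Bayes step added a prior worth 10.9. Means and standard deviations (SD) in the text are of linear intensities, and changes are differences of log2 means with their standard error (SE). The 9 comparisons were each mutant against WT and the mutants against each other in Tregs and in transduced cells, the difference between both systems in the effect of each allele, and WT Tregs against WT-transduced cells. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, and adjusted p of single genes are limma's.

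Genes named in the text follow a rule. It takes Foxp3 in every comparison, the 10 largest rises and the 10 largest falls among called genes whose arrays did not overlap between the groups, up to 10 genes changed by both alleles in a system or by an allele in both systems, and up to 4 members of each called gene list. Where fewer genes than that passed, all of them were taken. Predicted genes and clone names were left out of the sentences, and genes named outside the rule are marked as such.

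The 23 gene lists cover genes high in Tregs and genes low in Tregs (the Treg signature), effector Tregs, resting Tregs, the Th1, Th2, Th17 and follicular helper (Tfh) programmes, interferon response, proliferation, the early response to T cell receptor signals, IL-2 and STAT5 targets, the TGF-beta and integrin axis, glycolysis, cholesterol synthesis, heat shock, T cell identity, and markers of B cells, plasma cells, myeloid cells, dendritic cells, CD8+ T and NK cells and erythroid cells. Of these, 21 had at least 5 tested members and 2, plasma cell and erythroid markers, had 4 each and were not tested. Of the 29 tested genes of the Treg signature, 7 also stand in the effector list. Lists were tested with limma's camera, which compares the list with all other genes at a preset correlation of 0.01 between its members, and adjusted over the lists within a comparison. Camera was repeated with a correlation estimated per list, and fry was run beside it, which tests whether a list's genes move on balance in one direction without comparing them with other genes. Members were also counted with limma's p adjusted over the list alone.

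Changes of both alleles share the WT arrays of their system, which by itself makes them correlate. The correlation and covariance expected with no allele effect were therefore simulated with 100 draws from each gene's residual spread. With an array left out, the expected correlation was computed from the number of arrays left in each group, a step added after the values had been seen. Because each WT group has 2 arrays, the controls were not split between the alleles, and part of any excess over the simulation may come from the controls used for both. Overlaps of called genes between comparisons with no array in common are given with the number expected if the calls were independent.

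The pipeline was tested on simulated data, with 200 of 8918 genes changed in each of 10 simulations. For M354 and M176 Tregs against WT it recovered 61.6% and 65.8% of genes changed 1.5-fold, and 99.4% and 99.7% of those changed 2-fold. For M354 and M176 in transduced cells the shares were 65.4% and 65.3% at 1.5-fold and 99.8% for both at 2-fold. For the differences between systems they were 21.3% for M354 and 16.1% for M176 at 1.5-fold, 85.2% and 87.5% at 2-fold, and 99.7% and 99.8% at 3-fold. False calls made up between 5.01% and 6.5% of all calls. A shift of 0.3 (log2) given to the effector Treg list was called in 20 of 20 simulations, and 2 of 340 tests of unchanged lists were called. Noise was drawn independently for each gene in these simulations. In the data the correlation estimated within a list was 0.4 for proliferation genes and 0.478 for B cell markers. The simulations therefore do not give the rate of false list calls for lists whose members vary together.

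Alternatives tried were quantile and cyclic loess normalization of the deposited values, no filter and a filter at percentile 75, a fit of only the arrays of a system, the replicate number as a block, trended and robust variances, array weights, the mean over a gene's probe sets, every probe set as a feature, an adjusted p under 0.10, a change of at least 1.5-fold, and each array left out in turn. These, the comparisons, the gene lists and the naming rule were fixed before the data were examined. The mean level of small nucleolar RNA genes (snoRNAs) as a covariate, a test without small RNA and ribosomal protein genes, and a block with the replicate numbers of M354-transduced cells exchanged were added after the data had been seen. The second WT Treg array, already left out in turn, was singled out at that stage. Classes of RNA and sex-linked genes were also looked at only then.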

Results

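Gene expression was measured on 12 arrays, 2 for each of 6 groups. The Treg groups held cells sorted, and sorted again, as live CD4+ CD25-high cells from the spleens of mice with WT, M354 or M176 Foxp3, the transcription factor that defines this lineage. The others were WT conventional CD4+ T cells that had been transduced in culture with WT, M354 or M176 Foxp3 and sorted for high Thy1.1, the marker carried by the retrovirus. No transduction without Foxp3 was part of the design. The labels describe all 12 samples as from male C57BL/6 mice aged 6 weeks and do not say whether the arrays of a group came from separate animals or cultures. The p-values therefore measure the spread between these samples, which may be technical. Every called gene named below in a comparison of a pair of groups had both arrays of one group above both arrays of the other, which chance alone gives for 1 gene in 3.

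Foxp3 itself was measured at similar levels in 5 of the 6 groups. Its intensity was 5620 ± 414 in WT Tregs and 5738 ± 358 in M354 Tregs (SD, n = 2 each), a log2 difference of 0.03 with an SE of 0.13 (limma adjusted p = 0.972). In M176 Tregs it was 3381 ± 85.5, and Foxp3 fell by 0.73 against WT (SE 0.13, adjusted p = 0.000554). The transduced cells held 6054 ± 154 with WT, 5580 ± 340 with M354 and 5448 ± 304 with M176 Foxp3, and neither mutant differed from WT (log2 -0.12 and -0.15, adjusted p = 0.838 and 1). WT Tregs and WT-transduced cells differed by -0.11 (adjusted p = 0.545). The difference between systems in the effect of M176 on Foxp3 was -0.58 (SE 0.18), which did not pass (adjusted p = 0.0664), and that of M354 was 0.15 (adjusted p = 0.869).

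**Figure D1:**
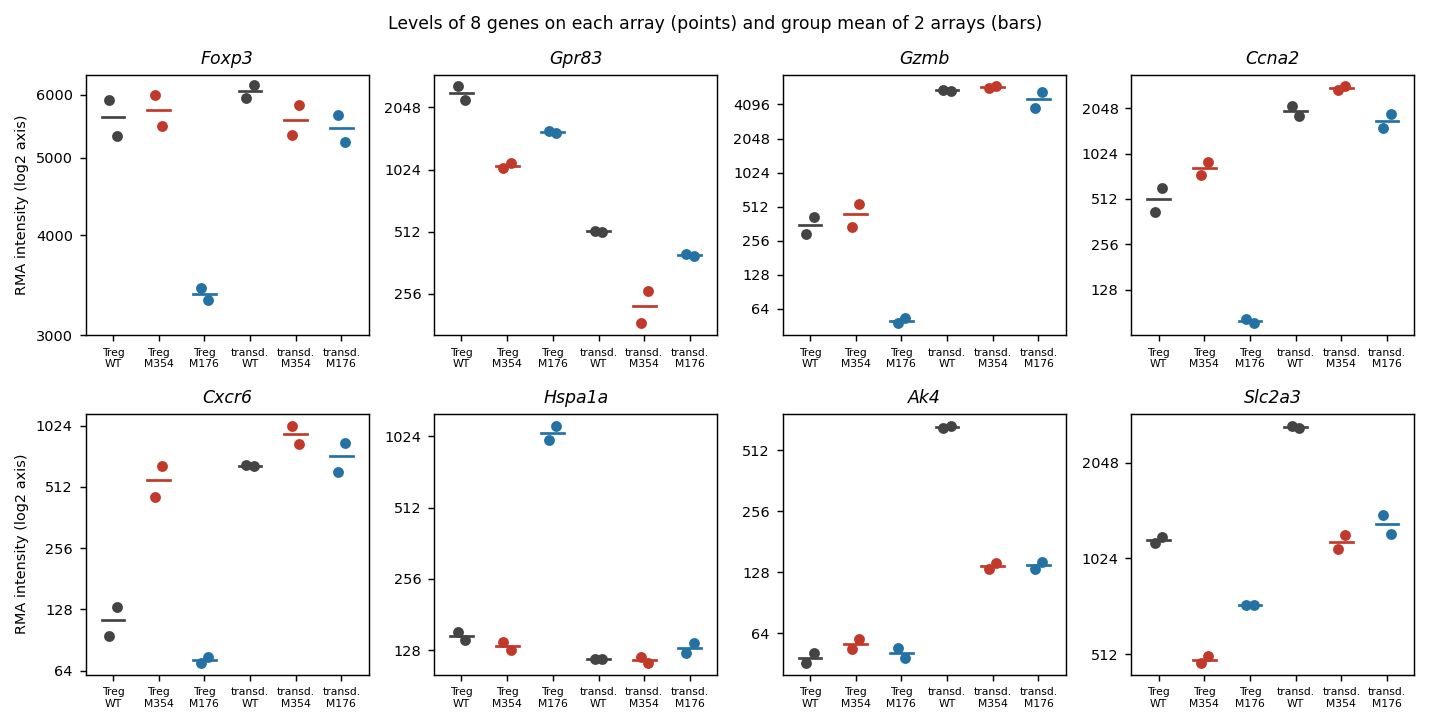
Intensity (log2 axis) of 8 genes in each of the 12 arrays, with a point per array and a bar at the mean of the 2 arrays of a group. Foxp3 averaged 3381 in M176 Tregs and between 5448 and 6054 in the other groups, and Ak4 averaged 666.5 in WT-transduced cells against 137.8 and 138.3 with M354 and M176.

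In M354 Tregs the chemokine receptor Cxcr6 rose from 113.6 ± 26.5 to 553.9 ± 136 (SD, n = 2 each; log2 2.28, SE 0.19, adjusted p = 6.41e-06), and Cxcl10, which encodes a ligand of the receptor Cxcr3, rose from 256.5 ± 15.8 to 1054 ± 178 (log2 2.03, adjusted p = 2.23e-06). The ligand-activated transcription factor Ahr rose from 639.7 ± 70.5 to 1758 ± 36.1 (log2 1.46, adjusted p = 3.16e-05), and the opioid peptide precursor Penk from 1732 ± 404 to 4775 ± 491 (log2 1.48, adjusted p = 0.000247). Id2, an inhibitor of E proteins, rose by 1.34 and Tnfsf8, a ligand of the tumour necrosis factor family, by 1.27. The glucose transporter gene Slc2a3 fell from 1168 ± 38.4 to 492.2 ± 15.8 (log2 -1.25, adjusted p = 3.16e-05), and the orphan receptor Gpr83, a marker of Tregs, from 2406 ± 258 to 1069 ± 38.7 (log2 -1.17, adjusted p = 0.000247). Cd7 fell by 1.14, the ubiquitin ligase gene Mid1 by 1.41 and the nucleotide-sugar transporter gene Slc35d1 by 1.41. The widest fall was that of the peptide transporter Slc15a2 (log2 -2.20, SE 0.43, adjusted p = 0.00951), whose call was lost without WT Treg replicate 1 (adjusted p = 0.0878).

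Proliferation genes were higher as a group in M354 Tregs, with a mean log2 change of 0.449 over 30 genes (camera adjusted p = 9.93e-22, or 0.201 with an estimated correlation). Over all genes 4 of them rose and 0 fell, and 18 rose when adjusted over the list alone. Stmn1 rose by 0.89 and Cks2 by 0.77, calls that were lost without WT Treg replicate 1 (adjusted p = 0.139 and 0.116) or M354 Treg replicate 2 (0.165 and 0.0731), and for Cks2 without M354 Treg replicate 1 (0.0884). Resting Treg genes were lower (8 genes, mean -0.428, adjusted p = 1.88e-05, or 0.201 with an estimated correlation), with 2 falling over all genes and 6 when adjusted over the list alone. The falls were in Satb1, a chromatin organiser (-0.90, adjusted p = 0.00118), and the interleukin-7 receptor gene Il7r (-0.79, adjusted p = 0.00268), while Bach2 at -0.47 did not pass (adjusted p = 0.173).

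Effector Treg genes were higher in M354 Tregs (18 genes, mean 0.169, adjusted p = 0.000361, or 0.229 with an estimated correlation), with 2 rises, 0 falls and 4 rises against 1 fall when adjusted over the list alone. Ebi3, a cytokine subunit, rose by 0.97 (adjusted p = 0.0043) and the inhibitory receptor Tigit by 0.56 (adjusted p = 0.0447). The call of the list was lost without M354 Treg replicate 2 (adjusted p = 0.0713), as was that of Ebi3 (0.0755), and that of Tigit without any one mutant array of either system or WT Treg replicate 2 (0.0563 to 0.426). Th2 genes were higher (7 genes, mean 0.303, adjusted p = 0.000297, or 0.229 with an estimated correlation), with 1 rise over all genes and 4 rises and 1 fall when adjusted over the list alone. Maf at 0.39 and Ccr8 at 0.44 did not pass over all genes. Early T cell receptor response genes were lower (24 genes, mean -0.194, adjusted p = 0.00568, or 0.608 with an estimated correlation; 0.0938 without WT Treg replicate 1), with 0 rising and 2 falling, and 1 rising and 7 falling when adjusted over the list alone. The 2 falls were of Jun (-0.63) and Fos (-0.55), subunits of the AP-1 transcription factor. Neither was called without M354 Treg replicate 1 (adjusted p = 0.205 and 0.164), WT Treg replicate 1 (0.146 and 0.213) or WT Treg replicate 2 (0.0664 and 0.123), and Fos not without M354 Treg replicate 2 (0.141) or either M176 Treg array (0.0671).

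Genes high in Tregs (29 genes, mean 0.0769) were called higher in M354 Tregs at adjusted p = 0.0415 (adjusted p = 0.619 with an estimated correlation), with 3 rises and 1 fall, or 8 and 4 when adjusted over the list alone. That call was lost without M354 Treg replicate 2 (adjusted p = 0.418), WT Treg replicate 1 (0.0823) or WT Treg replicate 2 (0.126), and with no filter (0.294). The Th1 list (6 genes, mean 0.404, 1 rise, adjusted p = 0.0277, or 0.497 with an estimated correlation) and the Th17 list (6 genes, mean 0.259, 1 rise, adjusted p = 0.0277, or 0.229 with an estimated correlation) owed their single rises to Cxcr6 and Ahr. The Th1 call was lost without M354 Treg replicate 2 (adjusted p = 0.216) or WT Treg replicate 1 (0.09), and the Th17 call without either of these (0.0713 and 0.128) or M354 Treg replicate 1 (0.0802). Both were also lost with no filter (0.0651 and 0.0671) and with quantile normalization (0.0702 for both). B cell markers were lower (13 genes, mean -0.458, adjusted p = 0.00818, or 0.608 with an estimated correlation), with 0 rises and 1 fall, Cd72 at -0.85, itself not called without M354 Treg replicate 1 (0.113) or WT Treg replicate 1 (0.0531). WT Treg replicate 2 held more B cell transcript than replicate 1, with Cd79a at 399 against 93.8, H2-Aa at 557 against 68.2 and Ms4a1 at 213 against 38. Without it the direction of the list turned and it was not called (adjusted p = 0.0739), nor was it without M354 Treg replicate 2 (0.216).

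The other lists were not called in M354 against WT Tregs. Their adjusted p were 0.243 for interferon response (0 rose and 0 fell of 24), 0.328 for heat shock (0 and 0 of 10), 0.616 for T cell identity (0 and 0 of 12), 0.694 for cholesterol synthesis (0 and 0 of 16), 0.974 for the TGF-beta and integrin axis (2 and 1 of 16), 0.974 for myeloid markers (0 and 0 of 6) and 0.328 for dendritic cell markers (0 and 1 of 6). For genes low in Tregs (0.512), Tfh (0.694), IL-2 and STAT5 targets (0.95), glycolysis (0.805) and CD8+ T and NK cell markers (0.328) the median, mean and test of the list differed in sign. The median change of the 4 plasma cell markers, not tested, was 0.01 and that of the 4 erythroid markers 0.39, with 0 genes called in either.

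Limma called 161 genes between M354 and WT Tregs, 79 higher and 82 lower, and the split leaned either way with the setting. It was 141 and 80 with cyclic loess and 147 and 130 with quantile normalization, 44 and 29 without M354 Treg replicate 1, and 72 and 40 without WT Treg replicate 2. It was 38 and 57 without M354 Treg replicate 2, 40 and 55 without WT Treg replicate 1, and 55 and 77 with the filter at percentile 75.

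In M176 Tregs the cytotoxic protease gene Gzmb fell from 355.2 ± 88.4 with WT Foxp3 to 50.21 ± 3.72 (SD, n = 2 each; log2 -2.80, SE 0.21, adjusted p = 3.59e-07), and the inhibitory receptor gene Klrg1 from 720.7 ± 114 to 150.9 ± 30.2 (log2 -2.26, adjusted p = 6.58e-07). Ccna2, which encodes cyclin A2, fell from 511.5 ± 133 to 79.72 ± 4.04 (log2 -2.66, adjusted p = 5.66e-08), and the proliferation marker Mki67 from 503.5 ± 188 to 109.7 ± 4.33 (log2 -2.15, adjusted p = 3.7e-06). The chemokine receptor Ccr2 fell by 2.13, the kinesin gene Kif11 by 2.04 and the mitotic kinase gene Bub1 by 2.06. Gzmb and these genes ended near background (30.4 to 56.8), so the size of their falls is open. Hspa1a, which encodes an inducible heat shock chaperone, rose from 146.6 ± 8.37 to 1059 ± 107 (log2 2.85, SE 0.13, adjusted p = 5.38e-10).

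Several snoRNAs and ribosomal protein genes were among the other large rises in M176 Tregs. Rps21 rose from 349.4 ± 30.9 to 1995 ± 181 (log2 2.51, adjusted p = 8.14e-07) and Rpl24 by 2.33, while Snord15a and Snord22 rose by 2.39 and 2.36. Of 36 snoRNA and scaRNA genes tested 21 were called, all 21 higher, and of 56 ribosomal protein genes 38 were called, 36 of them higher. The median log2 change was 1.15 over the snoRNA class and 0.644 over the ribosomal proteins, and it stayed positive with quantile (1.03 and 0.434) and cyclic loess normalization (1.17 and 0.531). The mean log2 level of the snoRNAs was 9.98 and 10.04 on the M176 Treg arrays and between 8.66 and 8.87 on the other Treg arrays, so that every gene group below that separates M176 from the other Tregs moves together with it.

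Proliferation genes fell as a group in M176 Tregs (30 genes, 18 falling and 0 rising, 20 falling when adjusted over the list alone, mean log2 -0.849, adjusted p = 2.9e-10, or 0.256 with an estimated correlation). Effector Treg genes fell likewise (18 genes, 11 falling and 0 rising, 13 falling when adjusted over the list alone, mean -0.851, adjusted p = 5.88e-08, or 0.256 with an estimated correlation), with Tigit at -1.38 and the transcription factor Maf at -1.08. Of 29 genes high in Tregs 15 fell and 0 rose, and the same number fell when adjusted over the list alone (mean -0.480, adjusted p = 5.17e-05, or 0.268 with an estimated correlation). Among these the integrin gene Itgb8, whose product activates TGF-beta, fell by 0.87. Genes low in Tregs rose (13 genes, 4 rising and 1 falling, 5 and 1 when adjusted over the list alone, mean 0.363, adjusted p = 0.0174, or 0.406 with an estimated correlation). Dapl1 rose from 596.6 ± 59.8 to 2259 ± 1.62 (log2 1.92) and the cytokine gene Il2 by 0.89, whereas Il7r fell by 0.65. Quantile normalization ended the call of the genes low in Tregs (adjusted p = 0.0657).

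The Th2 list (7 genes, 4 falling and 0 rising, 6 falling when adjusted over the list alone, mean -0.652) fell at adjusted p = 0.000439 (adjusted p = 0.256 with an estimated correlation), with the chemokine receptors Ccr4 and Ccr8 at -1.45 and -0.83. The Th17 list (6 genes, 3 falling and 0 rising in both counts, over all genes and adjusted over the list alone, mean -0.521) fell at adjusted p = 0.0218 (adjusted p = 0.256 with an estimated correlation, 0.0636 with quantile normalization), with Ccr6 at -1.59 and Ahr at -0.87. Heat shock genes rose (10 genes, 7 rising and 0 falling, 8 rising when adjusted over the list alone, mean 0.799, adjusted p = 5.17e-05, or 0.256 with an estimated correlation), with the mitochondrial co-chaperone Hspe1 at 1.62 and Dnajb1 at 0.78. Interferon response genes rose (24 genes, 9 rising and 0 falling, 11 rising when adjusted over the list alone, mean 0.345, adjusted p = 0.000521, or 0.256 with an estimated correlation), with Ifi27l2a at 1.35, Rtp4 at 0.92 and Ifit3 at 0.76. Cholesterol synthesis genes rose (16 genes, 3 rising and 0 falling in both counts, mean 0.324, adjusted p = 0.0042, or 0.313 with an estimated correlation, and 0.0836 with the snoRNA level as a covariate). Their 3 rises, Msmo1 at 0.76, Fdft1 at 0.53 and Ebp at 0.46, were not called without M176 Treg replicate 1 (adjusted p = 0.113, 0.105 and 0.138), and Ebp not without any other Treg array of either group (0.0596 to 0.122).

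B cell markers fell in M176 Tregs (13 genes, 4 falling and 0 rising, 9 falling when adjusted over the list alone, mean -0.690, adjusted p = 0.000991, or 0.406 with an estimated correlation), and Cd74, the invariant chain of MHC class II, fell by 1.02. Without WT Treg replicate 2, which held B cell transcripts, the list was not called (adjusted p = 0.412). Not called were the resting Treg (adjusted p = 0.603), Th1 (0.132), Tfh (0.636), IL-2 and STAT5 (0.387), TGF-beta and integrin (0.387), glycolysis (0.613), T cell identity (0.538), myeloid (0.636), dendritic cell (0.387) and CD8+ T and NK cell lists (0.533). The early T cell receptor response list (0.387) had a median of -0.09 and a mean of 0.11.

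In all, 2207 genes were called between M176 and WT Tregs by limma, 1196 higher and 1011 lower. Quantile normalization moved the split to 1125 higher and 1451 lower. With the snoRNA level as a covariate 363 genes were called, 320 of them among the 2207. Among Tregs that level nearly coincides with M176, which widens the SE, so the drop may in part be lost power. The count was lower with any 1 M176 or WT Treg array left out.

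**Figure D2:**
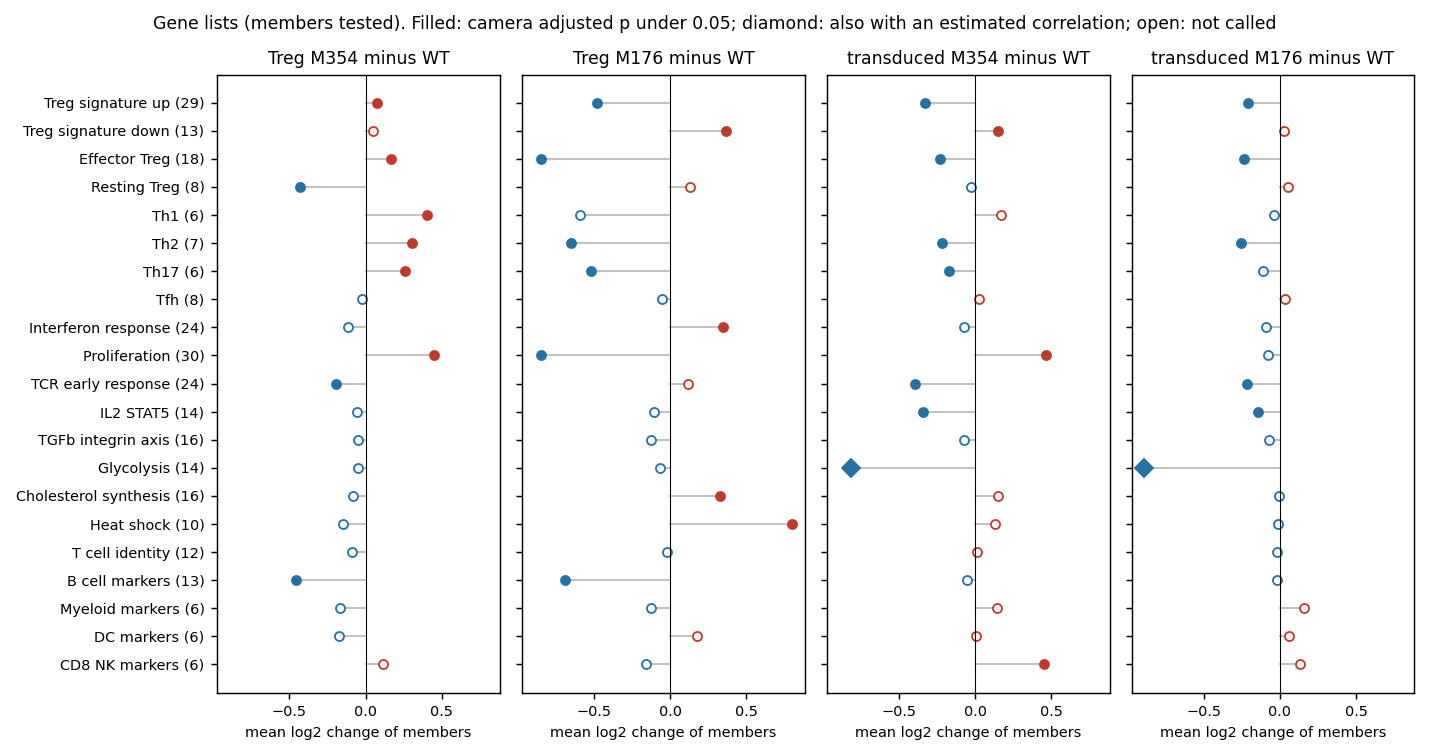
Mean log2 change against WT of the tested members of 21 gene lists in M354 and M176 Tregs and in M354- and M176-transduced cells. Filled symbols mark a camera adjusted p under 0.05, diamonds those that also passed with an estimated correlation, which only glycolysis did (means -0.818 and -0.890 in transduced cells), and open symbols lists not called.

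Several gene lists differed from WT in opposite directions in M354 and M176 Tregs, and none of the list calls among Tregs held with an estimated correlation. Against M176, M354 Tregs had higher Ccna2 (818.7 ± 107 against 79.72 ± 4.04, SD, n = 2 each; log2 3.35, adjusted p = 2.02e-09), Gzmb (439.4 ± 144 against 50.21 ± 3.72; 3.09, adjusted p = 3.08e-08), Cxcr6 (log2 2.92), Ahr (2.34) and Penk (2.32). Gzmb lay near background with M176. Foxp3 was higher by 0.76 (SE 0.13, adjusted p = 0.000275). Hspa1a was lower in M354 Tregs (133.5 ± 7.06 against 1059 ± 107, log2 -2.98, adjusted p = 2.53e-10), as were the chitinase-like gene Chil5 (48.29 against 256.2, log2 -2.41) and Fos (129.7 against 588.6, log2 -2.18). Snord22 and Rps21 were lower by -2.40 and -2.55, with all 24 called snoRNA and scaRNA genes lower.

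Of 30 proliferation genes 25 were higher in M354 than in M176 Tregs and 0 lower (adjusted p = 1.6e-20, or 0.113 with an estimated correlation), with Mki67 at 2.66. Effector Treg genes were higher for 15 and lower for 0 of 18 (adjusted p = 3.14e-11, or 0.113 with an estimated correlation), with Klrg1 at 2.27 and Tigit at 1.95. All 7 Th2 genes were higher (adjusted p = 6.76e-07, or 0.113 with an estimated correlation), as were 3 of 6 Th17 genes (adjusted p = 0.0019, or 0.113 with an estimated correlation), with 0 lower in either. These 4 counts were the same or differed little when adjusted over the list alone.

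Genes high in Tregs were higher in M354 than in M176 Tregs for 14 and lower for 3 of 29, or 16 and 3 when adjusted over the list alone (adjusted p = 6.29e-06, or 0.21 with an estimated correlation). Heat shock genes were lower for 7 and higher for 1 of 10, or 8 and 1 adjusted over the list alone (adjusted p = 0.00011, or 0.21 with an estimated correlation), with Hspe1 at -1.61. Interferon response genes were lower for 13 and higher for 0 of 24, or 15 and 0 adjusted over the list alone (adjusted p = 0.000129, or 0.21 with an estimated correlation), with Ifi27l2a at -1.70 and Usp18, a brake on interferon signals, at -0.98. Cholesterol synthesis genes were lower for 7 and higher for 0 of 16, or 8 and 0 adjusted over the list alone (adjusted p = 0.00485, or 0.288 with an estimated correlation, and 0.0868 with the snoRNA level as a covariate), with Msmo1 at -0.98. Resting Treg genes were lower for 5 and higher for 0 of 8 (adjusted p = 0.0137, or 0.272 with an estimated correlation), with Id3 at -1.65, Klf2 at -1.14 and Satb1 at -1.02. Th1 genes were higher for 3 and lower for 1 of 6 (adjusted p = 0.0275, or 0.328 with an estimated correlation). Early T cell receptor response genes were lower for 9 and higher for 2 of 24 (adjusted p = 0.0293, or 0.491 with an estimated correlation), with Cd69 at -1.14 and Nr4a2 at 0.92. Quantile normalization ended the calls of these last 3 lists (adjusted p = 0.0895, 0.104 and 0.0847), and the last was also lost without M176 Treg replicate 2 (0.0782).

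Between M354 and M176 Tregs limma called 2747 genes, 1129 higher and 1618 lower, against 1585 and 1442 with quantile normalization, 1451 and 1420 with cyclic loess normalization and 1688 and 1607 without a filter. The count was 570 with the snoRNA level as a covariate. It also fell with any 1 M354 or M176 Treg array left out.

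Some genes changed in the same direction with both alleles in Tregs. The transporter genes Slc35d1 (-1.41 with M354, -1.26 with M176), Slc2a3 (-1.25 and -0.68) and Slc28a2b (-1.18 and -0.95) fell with both, as did Mid1 (-1.41 and -0.75) and the phosphatase gene Ptprj (-0.60 and -1.57). The proton pump subunit gene Atp6v0d2 fell from 54.2 in WT Tregs to 21.6 with M354 and 30.0 with M176, levels also seen for Y-linked genes on arrays that express none (11.8 to 30.4), so the size of its fall is not determined. Tnfsf8 rose with both (1.27 and 0.80), as did Srsy, a Y-linked transcript near background in WT Tregs (43.1). The fall of Ptprj with M354 was lost without any one Treg or M176-transduced array (adjusted p = 0.0558 to 0.215). In total 30 genes fell and 15 rose with both alleles, and 20 rose with M354 and fell with M176, Ahr, Cxcr6, Penk and Ccna2 among them. A further 8 fell with M354 and rose with M176. Both alleles were set against the same WT arrays, so no number expected by chance is given and part of the changes in the same direction may come from these arrays.

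Cells transduced with M354 Foxp3 had lower levels of several genes than cells transduced with WT Foxp3, glycolysis genes among them. The adenylate kinase gene Ak4 fell from 666.5 ± 12.7 to 137.8 ± 6.94 (SD, n = 2 each; log2 -2.28, SE 0.13, adjusted p = 2.35e-08), Ndrg1 from 1844 ± 103 to 443.1 ± 34.1 (log2 -2.06, adjusted p = 5.47e-08) and the mitophagy gene Bnip3 from 1981 ± 122 to 610.1 ± 13.3 (log2 -1.70, adjusted p = 7.3e-05). Egln3, an oxygen-sensing hydroxylase, fell by 1.62, the angiogenic factor Vegfa by 1.53 and Slc2a3 by 1.21. Gpr83 fell from 513.7 ± 5.11 to 223.7 ± 55.8 (log2 -1.22, adjusted p = 0.000243) and the costimulatory receptor gene Tnfrsf9 from 2296 ± 180 to 1043 ± 56.7 (log2 -1.14, adjusted p = 0.000395). Among the rises, which reached 1.06, were Lypd6b at 0.88 (adjusted p = 0.000858) and the sialyltransferase gene St3gal6 at 0.86 (adjusted p = 0.00373).

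Of 14 glycolysis genes 10 fell and 0 rose with M354, and 13 fell when adjusted over the list alone (mean -0.818, adjusted p = 1.88e-26). This call also held with an estimated correlation (adjusted p = 0.0134), and with Hk2, the inducible hexokinase, at -1.07 it included the entry step of the pathway. In the same comparison the median log2 change was 0.303 over 36 snoRNA and scaRNA genes and 0.311 over 56 ribosomal protein genes, and with M176 it was 0.274 and 0.216. Early T cell receptor response genes fell (24 genes, 6 falling and 0 rising, 13 falling when adjusted over the list alone, adjusted p = 1.97e-16, or 0.0651 with an estimated correlation), with Jun and Junb at -0.75 and -0.74. The falls of Jun and Junb were lost without M354-transduced replicate 1 (adjusted p = 0.15 for Jun), M354-transduced replicate 2 (0.0877 for Junb) or WT-transduced replicate 2 (0.0557 for Junb). Genes high in Tregs fell (29 genes, 9 falling and 0 rising, 14 falling and 1 rising when adjusted over the list alone, mean -0.328, adjusted p = 1.53e-12, or 0.0678 with an estimated correlation). Lrrc32, which tethers latent TGF-beta to the cell surface, changed by -0.79 (adjusted p = 0.0229). This call was lost without M354-transduced replicate 1 (0.231), M354-transduced replicate 2 (0.0689) or WT-transduced replicate 2 (0.242).

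IL-2 and STAT5 targets fell with M354 (14 genes, 2 falling and 0 rising, 6 falling when adjusted over the list alone, adjusted p = 5.19e-09, or 0.0651 with an estimated correlation), with the receptor gene Tnfrsf8 at -0.86. Effector Treg genes fell (18 genes, 3 falling and 0 rising, 6 falling and 1 rising when adjusted over the list alone, adjusted p = 8.41e-05, or 0.128 with an estimated correlation), with Nfil3 at -0.86, while Tigit at -0.53 did not pass (adjusted p = 0.0727). Proliferation genes rose (30 genes, 4 rising and 0 falling, 19 rising when adjusted over the list alone, adjusted p = 1.99e-18, or 0.0962 with an estimated correlation). CD8+ T and NK cell markers rose (6 genes, 2 rising and 0 falling in both counts, adjusted p = 0.000847, or 0.0651 with an estimated correlation). Their rises were of Gzma (1.06, adjusted p = 0.0141) and the lectin receptor gene Klrd1 (1.06, adjusted p = 0.00735), lost without WT-transduced replicate 2 (0.2 and 0.0936), M354-transduced replicate 2 for Gzma (0.153) or M354-transduced replicate 1 for Klrd1 (0.15).

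The Th2 list was called lower at adjusted p = 0.0107 (7 genes, 2 falling and 0 rising, 3 falling and 1 rising adjusted over the list alone, adjusted p = 0.34 with an estimated correlation). This call was lost without M354-transduced replicate 1 (0.14) or WT-transduced replicate 1 (0.0533). Genes low in Tregs (13 genes, 0 called, 2 rising when adjusted over the list alone) were called higher and the Th17 list (6 genes, 0 called in either count) lower, both at adjusted p = 0.0486, with adjusted p = 0.48 and 0.15 with an estimated correlation. Quantile normalization ended both calls (0.163 and 0.0635), as did leaving out M354-transduced replicate 2 (0.229 and 0.202), WT-transduced replicate 1 (0.0736 and 0.103) or WT-transduced replicate 2 (0.131 and 0.108). The call of genes low in Tregs was also lost with the replicate block (0.0557) and with the fit per system (0.0566). Of the lists not called, cholesterol synthesis came nearest (adjusted p = 0.0506), and median, mean and test differed in sign for T cell identity and dendritic cell markers. Between M354 and WT limma called 119 genes, 32 higher and 87 lower. Both count and split depended on single arrays, with 80 higher and 60 lower without WT-transduced replicate 1, 2 and 63 without WT-transduced replicate 2, and 5 and 37 without M354-transduced replicate 1.

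In M176-transduced cells Ak4 fell to 138.3 ± 7.15 (SD, n = 2; log2 -2.27, SE 0.13, adjusted p = 2.45e-08), Ndrg1 to 454.5 ± 28.5 (log2 -2.02, adjusted p = 7.31e-08), Bnip3 to 576.8 ± 118 (log2 -1.79) and Slc2a3 to 1311 ± 128 (log2 -1.02, adjusted p = 0.000213). Egln3 fell by 1.78, Vegfa by 1.51, Hk2 by 1.20 and the collagen-modifying enzyme gene Plod2 by 1.44. The single rise was that of Ctsg, which encodes cathepsin G, from 61.79 ± 4.01 to 161.2 ± 8.92 (log2 1.38, SE 0.16, adjusted p = 0.000101). Tnfrsf9 changed by -0.98 (adjusted p = 0.00186). This call was lost without M176-transduced replicate 1 (adjusted p = 0.0599).

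Glycolysis genes fell with M176 for 9 and rose for 0 of 14 genes, and 13 fell when adjusted over the list alone (mean -0.890, adjusted p = 1.23e-39). The call held with an estimated correlation (adjusted p = 0.00436). Genes high in Tregs were lower as a list (29 genes, 1 falling and 0 rising in both counts, adjusted p = 2.39e-07, or 0.282 with an estimated correlation). Early T cell receptor response genes were lower as well (24 genes, 0 called, 4 falling when adjusted over the list alone, adjusted p = 8.04e-07, or 0.282 with an estimated correlation). Effector Treg genes were lower (18 genes, 2 falling and 0 rising, 6 falling when adjusted over the list alone, adjusted p = 2.55e-05, or 0.282 with an estimated correlation). Th2 genes were also lower (7 genes, 0 called, 2 falling when adjusted over the list alone, adjusted p = 0.000531, or 0.282 with an estimated correlation). IL-2 and STAT5 targets were lower (14 genes, 1 falling and 0 rising in both counts, adjusted p = 0.0146, or 0.387 with an estimated correlation). The call did not hold without M176-transduced replicate 2 (0.283), WT-transduced replicate 2 (0.126) or with the snoRNA level as a covariate (0.0576). Proliferation genes were not called (adjusted p = 0.341). Median, mean and test differed in sign for the Th1, cholesterol synthesis and B cell lists, which were not called either. Limma called 46 genes, 1 higher and 45 lower. The number was 26 without M176-transduced replicate 1, 23 without M176-transduced replicate 2 and 27 without WT-transduced replicate 1.

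Of the genes lower with M354 (87) and with M176 (45) in transduced cells 39 were shared, with Ak4, Ndrg1, Bnip3, Egln3, Vegfa, Ero1a and Mgarp among them. The WT-transduced arrays were used in both comparisons, so no number expected by chance is given and part of the overlap may come from these arrays.

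M354- and M176-transduced cells differed from each other in 7 genes. Gzmc, a granzyme gene, was higher with M354 (665.3 ± 48.3 against 333.5 ± 0.22, SD, n = 2 each; log2 0.99, adjusted p = 0.024), as were the kinesin gene Kif4 (0.99), the kinetochore gene Zwilch (0.87), Shcbp1 (0.81) and Lypd6b (0.79). Ctsg was lower with M354 (59.27 ± 7.74 against 161.2 ± 8.92, log2 -1.45, adjusted p = 0.000585), and so was Gpr83 (223.7 ± 55.8 against 394.9 ± 6.24, log2 -0.84, adjusted p = 0.0461). The call of Ctsg held without any one array. Those of the other genes were lost without any one of the 4 M354- and M176-transduced arrays (adjusted p = 0.0746 to 0.612), except that Gpr83 was still called without M354-transduced replicate 2. Leaving out a mutant Treg array also ended the call of Gpr83 (0.0796 or 0.0799), and leaving out either M176 Treg array that of Zwilch (0.0544). Proliferation genes were higher with M354 as a list, with 0 of 30 called over all genes and 24 rising when adjusted over the list alone (mean 0.545, adjusted p = 3.65e-33, or 0.16 with an estimated correlation).

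Early T cell receptor response genes were lower with M354 than with M176 (0 called, 1 falling when adjusted over the list alone, adjusted p = 5.02e-08, or 0.22 with an estimated correlation). IL-2 and STAT5 targets were lower with M354 too (0 called, 1 falling when adjusted over the list alone, adjusted p = 3.11e-06, or 0.184 with an estimated correlation). So were genes high in Tregs (1 falling, 2 falling and 1 rising when adjusted over the list alone, adjusted p = 2.85e-05, or 0.356 with an estimated correlation). The CD8+ T and NK cell list (0 called, 2 rising when adjusted over the list alone) was higher at adjusted p = 0.0159 (adjusted p = 0.184 with an estimated correlation). The call was lost without M354-transduced replicate 1 (0.0699) or M176-transduced replicate 2 (0.0513). Cholesterol synthesis genes, 0 called in either count, were higher at adjusted p = 0.0365 (adjusted p = 0.523 with an estimated correlation), lost without M354-transduced replicate 1 (0.204), M176-transduced replicate 1 (0.268), with quantile normalization (0.0688) or with the snoRNA level as a covariate (0.0508). Glycolysis genes did not differ by the test (mean 0.0714, adjusted p = 0.525). Median, mean and test differed in sign for the effector Treg, Th2, Tfh, interferon response, TGF-beta and integrin and T cell identity lists, none of them called. The count of 7 genes (5 higher, 2 lower) was 1 with quantile normalization and 0 with the filter at percentile 75. It also moved with any 1 transduced array left out. By limma 462 of 8918 genes had an unadjusted p under 0.05, about as many as chance gives.

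A few genes fell with M354 in both systems. Gpr83 fell by 1.17 in Tregs and by 1.22 in transduced cells, and Slc2a3 by 1.25 and 1.21. Atp6v0d2 fell by 1.15 in transduced cells and to a level near background in Tregs. In total 10 genes fell with M354 in both systems, against 0.8 expected if the calls were independent, Fos, Jun, Ptprj, Elovl6, Chil5, Gbp2b and Zscan29 being the others. The proliferation genes Cks2 and Stmn1 rose in both, 2 genes against 0.283 expected. Without M354-transduced replicate 1, the calls of Fos, Jun, Elovl6, Chil5, Zscan29, Cks2 and Stmn1 in transduced cells were lost (adjusted p = 0.15 to 0.435). Bhlhe40, Plod2 and Prelid2 rose in M354 Tregs and fell in M354-transduced cells, 3 genes against 0.771 expected. With M176, 7 genes fell in both systems, against 5.1 expected, among them Slc2a3 (-0.68 in Tregs, -1.02 in transduced cells), and 4 rose in Tregs and fell in transduced cells, against 6.03 expected. Some overlaps between different alleles were also above the number expected. M176 Tregs and M354-transduced cells had 27 falls in common against 9.86 expected and 12 rises against 4.29, and 4 genes rose in M354 Tregs and fell in M176-transduced cells, against 0.399. Falls in common to M354 Tregs and M176-transduced cells numbered 1 against 0.414. The groups compared on both sides of these overlaps had no array in common. The calls still share 1 residual spread per gene, fitted over all 12 arrays, so the numbers expected can be too low.

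Across the 8918 genes tested, the changes with M354 and M176 in Tregs had a Pearson r of 0.0524 and a Spearman rho of 0.0662. The WT arrays in common give an r of 0.5 in simulation, but only with no allele effect. Changes particular to an allele lower that r by themselves, and the SD of the changes was 0.424 with M176 against 0.223 with M354. The observed r is therefore not comparable with 0.5, whereas the covariances are. The covariance of the changes with M354 and M176 in Tregs was 0.00494 against a simulated 0.0117. In transduced cells r was 0.66 and rho 0.566, with a covariance of 0.0266 against the same simulated value. This r was 0.44 without M176-transduced replicate 2 and 0.532 without M354-transduced replicate 1, where the WT arrays in common give 0.408, and 0.778 without WT-transduced replicate 1, where the single WT array gives 0.667. The effects of M354 in Tregs and in transduced cells, which have no array in common, had r = 0.179 and rho = 0.169, and those of M176 had r = 0.322 and rho = 0.309. These are 4 correlations across genes, and genes are not independent replicates. Without M354 Treg replicate 2 the r for M354 across systems was 0.0112 and that between alleles in Tregs was -0.0685, and r between alleles in Tregs was 0.191 without WT Treg replicate 1. Across systems r for M354 reached 0.323 without M354 Treg replicate 1, and r for M176 was 0.121 without M176-transduced replicate 2.

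**Figure D3:**
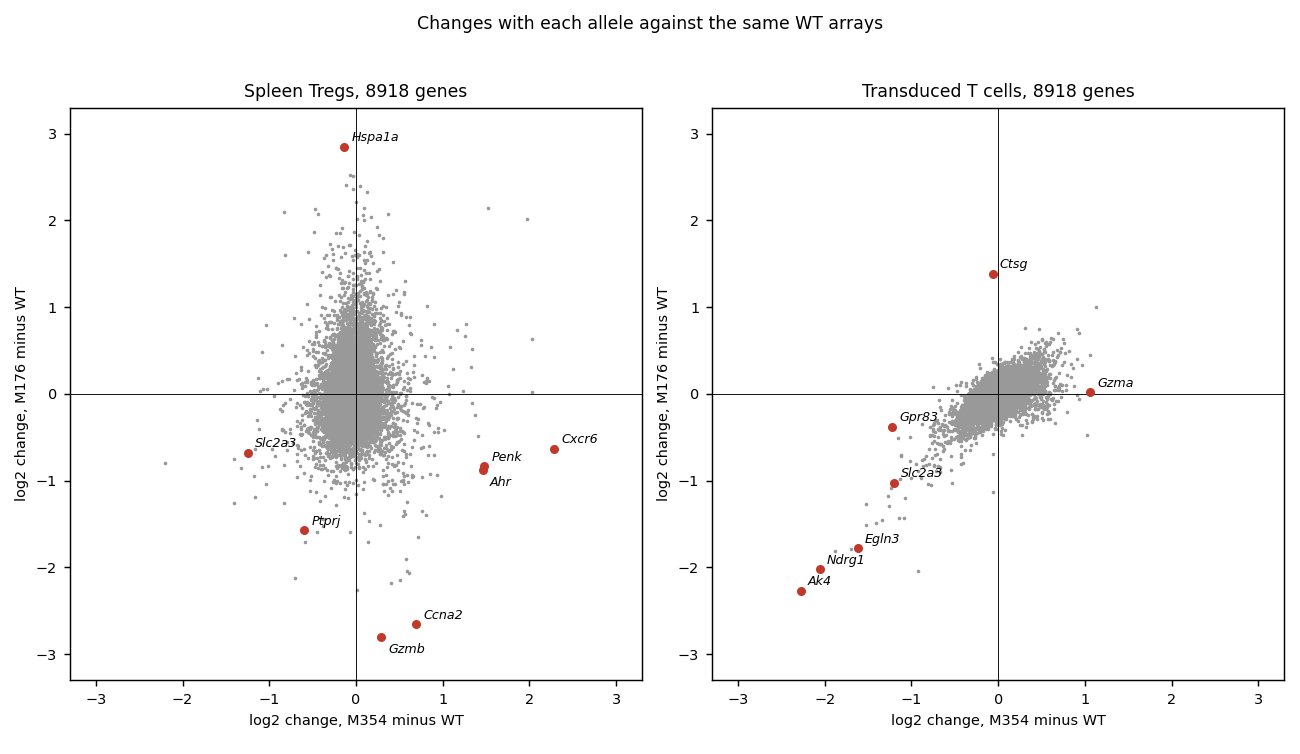
Log2 change of each of 8918 genes with M354 (horizontal axis) and M176 (vertical axis) against WT, in Tregs on the left and in transduced cells on the right, 1 point per gene. Pearson r was 0.0524 in Tregs and 0.66 in transduced cells, where Ak4 lay at -2.28 and -2.27.

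M354 effects differed most between systems for Cxcl10 and Ak4. The difference (change in Tregs minus that in transduced cells) was 2.59 for Cxcl10 (SE 0.22, adjusted p = 5.58e-06), which rose in Tregs. For Ak4, near background in Tregs, 2.50 (SE 0.18, adjusted p = 1.26e-06) restated the fall in transduced cells. Cxcr6 at 1.78 and Ahr at 1.67 were likewise higher, and Cd7 at -1.38 and the RNA transporter gene Sidt1 at -1.22 lower. Of 14 glycolysis genes 8 differed upward and 0 downward, or 9 and 1 when adjusted over the list alone (mean 0.771, adjusted p = 8.16e-19), and this call held with an estimated correlation (adjusted p = 0.0333). Genes high in Tregs differed upward for 4 and downward for 0 of 29, or 13 and 0 adjusted over the list alone (mean 0.405, adjusted p = 1.44e-14, or 0.0578 with an estimated correlation). Effector Treg genes differed upward for 5 and downward for 0 of 18 in both counts (mean 0.402, adjusted p = 2.5e-09, or 0.0578 with an estimated correlation), with Maf at 1.15 and Tigit at 1.10. Upward differences were also called for the Th2 list (1 of 7 up, 3 adjusted over the list alone, adjusted p = 6.27e-07, or 0.0905 with an estimated correlation) and for IL-2 and STAT5 targets (2 of 14 up, 4 up and 1 down adjusted over the list alone, adjusted p = 7.34e-06, or 0.113 with an estimated correlation).

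For M354 the early T cell receptor response list also differed upward (0 of 24 called, adjusted p = 2.01e-05, or 0.244 with an estimated correlation), as did the Th17 list (1 of 6 up, 2 adjusted over the list alone, adjusted p = 0.000708, or 0.0578 with an estimated correlation). Resting Treg genes differed downward (1 of 8, 2 adjusted over the list alone, adjusted p = 0.000817, or 0.137 with an estimated correlation). Proliferation genes did not differ between systems by the test (mean -0.02, adjusted p = 0.603), with a median, mean and test that differed in sign, as did those of the Tfh, interferon response and T cell identity lists. Limma called 96 genes, 74 upward and 22 downward. The count was 58 without M354 Treg replicate 1, 58 without WT Treg replicate 2 and 57 without M354-transduced replicate 1.

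For M176, Gzmb differed between systems by -2.52 (SE 0.29, adjusted p = 0.000122) and Ccna2 by -2.44 (SE 0.24, adjusted p = 2.55e-05). Klrg1 differed by -2.36 and Mki67 by -1.89. All fell in M176 Tregs, Gzmb to near background. Hspa1a differed by 2.70 (SE 0.18, adjusted p = 3.39e-07), Fos by 1.97 and Chil5 by 2.18. Ak4 differed by 2.35 and Ciart by 2.04, both of which fell in transduced cells, and Rps21 and Rpl24 by 1.99 and 1.98. With Ak4 near background in Tregs, its difference restates the fall in transduced cells. Proliferation genes differed downward for 12 and upward for 0 of 30, or 16 and 0 when adjusted over the list alone (mean -0.770, adjusted p = 1.76e-11, or 0.258 with an estimated correlation). Effector Treg genes differed downward for 6 and upward for 1 of 18, or 7 and 1 adjusted over the list alone (mean -0.616, adjusted p = 4.98e-05, or 0.233 with an estimated correlation). Glycolysis genes differed upward for 8 and downward for 0 of 14, or 12 and 0 adjusted over the list alone (mean 0.822, adjusted p = 1.05e-10, or 0.144 with an estimated correlation).

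Heat shock genes differed upward with M176 for 4 of 10, or 7 adjusted over the list alone (adjusted p = 4.33e-06, or 0.233 with an estimated correlation). Interferon response genes did so for 5 of 24 in both counts (adjusted p = 4.98e-05, or 0.233 with an estimated correlation) and early T cell receptor response genes for 3 of 24, or 7 adjusted over the list alone (adjusted p = 0.000803, or 0.331 with an estimated correlation). Cholesterol synthesis (1 of 16 up, 2 adjusted over the list alone, adjusted p = 0.00713, or 0.324 with an estimated correlation) and genes low in Tregs (3 of 13 up, 3 up and 1 down adjusted over the list alone, adjusted p = 0.0194, or 0.343 with an estimated correlation) differed upward as lists. Th2 genes differed downward for 3 of 7, or 4 adjusted over the list alone (adjusted p = 0.00713, or 0.324 with an estimated correlation). With the snoRNA level as a covariate the calls of cholesterol synthesis (0.0567) and Th2 (0.0726) were lost. Genes high in Tregs differed downward for 5 and upward for 1 of 29, or 6 and 2 adjusted over the list alone (adjusted p = 0.0381, or 0.465 with an estimated correlation). The call did not hold without M176 Treg replicate 2 (0.0768), M176-transduced replicate 2 (0.118) or with no filter (0.127). B cell markers differed downward for 1 of 13, or 2 adjusted over the list alone (adjusted p = 0.000541, or 0.331 with an estimated correlation), and not without WT Treg replicate 2 (0.444). Median, mean and test differed in sign for IL-2 and STAT5 targets, which were not called. Limma called 488 genes, 358 upward and 130 downward, or 320 and 220 with quantile normalization. The count was 170 with the snoRNA level as a covariate. It also fell without most single M176 or WT arrays.

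WT Tregs and conventional T cells transduced with WT Foxp3 had the same Foxp3 level within the spread between arrays. The interleukin-12 receptor gene Il12rb2 was lower in Tregs (47.4 ± 2.59 against 1264 ± 167, SD, n = 2 each; log2 -4.73, adjusted p = 1.28e-13), as were the phosphodiesterase gene Pde3b (log2 -4.57), a gene low in Tregs, Gzmb (355.2 ± 88.4 against 5452 ± 137, -3.96, adjusted p = 3.23e-10), Ak4 (-3.79) and Bnip3 (-3.55). Itgb8 was higher in Tregs (789.3 ± 111 against 54.88 ± 10.3, log2 3.85, adjusted p = 7.56e-12), as were Dtx1, a Notch pathway gene (2.98), Ccr6 (2.72), Klrg1 (2.72) and Penk (2.63). Thy1 was lower in Tregs by -1.06, and the transduced cells were sorted for the Thy1.1 marker of the vector. The sex-linked genes separated both systems: Xist, expressed from the inactive X chromosome of females, lay between 47.6 and 68.5 on the 6 Treg arrays and between 4015 and 5367 on the 6 transduced arrays, while the Y-linked Eif2s3y lay between 428 and 674 and between 11.8 and 15.0, although all labels give male. The Treg arrays thus carried a male pattern and the transduced arrays a female one. Spleen cells were also set against cultured, transduced cells, so the calls of this comparison only describe both groups and cannot be put down to cell type alone.

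Proliferation genes were lower in Tregs for 27 of 30 in both counts (adjusted p = 4.48e-16, or 0.142 with an estimated correlation) and glycolysis genes for all 14 of 14 (adjusted p = 1.33e-15), a call that held with an estimated correlation (adjusted p = 0.0471). The list of CD8+ T and NK cell markers was lower for 5 and higher for 0 of 6 in both counts (adjusted p = 8.65e-05) and also held (adjusted p = 0.0471), with Gzma at -2.84 and Cd8a at -2.13. Interferon response genes were higher for 13 and lower for 1 of 24, or 14 and 2 adjusted over the list alone (adjusted p = 1.12e-06, or 0.142 with an estimated correlation), with Ifit1 at 2.25 and Usp18 at 2.14. Effector Treg genes were lower for 11 and higher for 2 of 18 (adjusted p = 0.000133, or 0.142 with an estimated correlation). Th1 genes were lower for 4 and higher for 1 of 6 (adjusted p = 0.000133, or 0.142 with an estimated correlation), with Cxcr6 at -2.54. IL-2 and STAT5 targets were lower for 8 and higher for 0 of 14 (adjusted p = 0.00536, or 0.26 with an estimated correlation), with the kinase gene Pim2 at -1.46. Genes low in Tregs were lower for 9 and higher for 1 of 13 (adjusted p = 0.001, or 0.214 with an estimated correlation). As a list, genes high in Tregs were higher for 10 and lower for 5 of 29 (adjusted p = 0.00576, or 0.383 with an estimated correlation, and 0.0768 with no filter).

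T cell identity genes were higher in Tregs for 5 and lower for 1 of 12 (adjusted p = 0.0222, or 0.142 with an estimated correlation), with Trat1 at 1.12. The call was lost without WT Treg replicate 1 (0.0566), WT-transduced replicate 1 (0.059) or with no filter (0.134). Early T cell receptor response genes were higher for 7 and lower for 3 of 24 (adjusted p = 0.0457, or 0.471 with an estimated correlation), with the orphan nuclear receptor Nr4a1 at 1.79 and Fosl2 at -2.00. The call did not hold without the same arrays (0.115 and 0.0654) or with no filter (0.395). Tfh genes were higher for 4 and lower for 2 of 8 (adjusted p = 0.0487, or 0.166 with an estimated correlation), with Cxcr5 at 1.31 and Btla at 1.03. Their call was lost with quantile normalization (0.0546), without a filter (0.469) and without either M354 Treg array (0.0638), either M176-transduced array (0.0538) or WT-transduced replicate 1 (0.0576). The TGF-beta and integrin list (adjusted p = 0.0992) was not called, and its median and mean differed in sign.

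B cell and myeloid markers were not called between WT Tregs and WT-transduced cells (adjusted p = 0.354 and 0.204), with 5 of 13 and 3 of 6 lower in Tregs and 1 higher in each list. Their levels nevertheless followed the system on most arrays. The mean log2 level of B cell markers lay between 8.02 and 8.14 on the 6 transduced arrays and between 6.87 and 7.12 on 5 Treg arrays, with 8.13 on WT Treg replicate 2. That of myeloid markers lay between 8.34 and 8.74 on transduced and between 7.18 and 7.60 on Treg arrays. These levels per array were compared only after the values had been seen.

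Limma called 2695 genes, 968 higher and 1727 lower in Tregs, or 1302 and 1306 with quantile normalization and 1903 and 1813 with no filter. The number was lower with any 1 WT array left out.

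**Figure D4:**
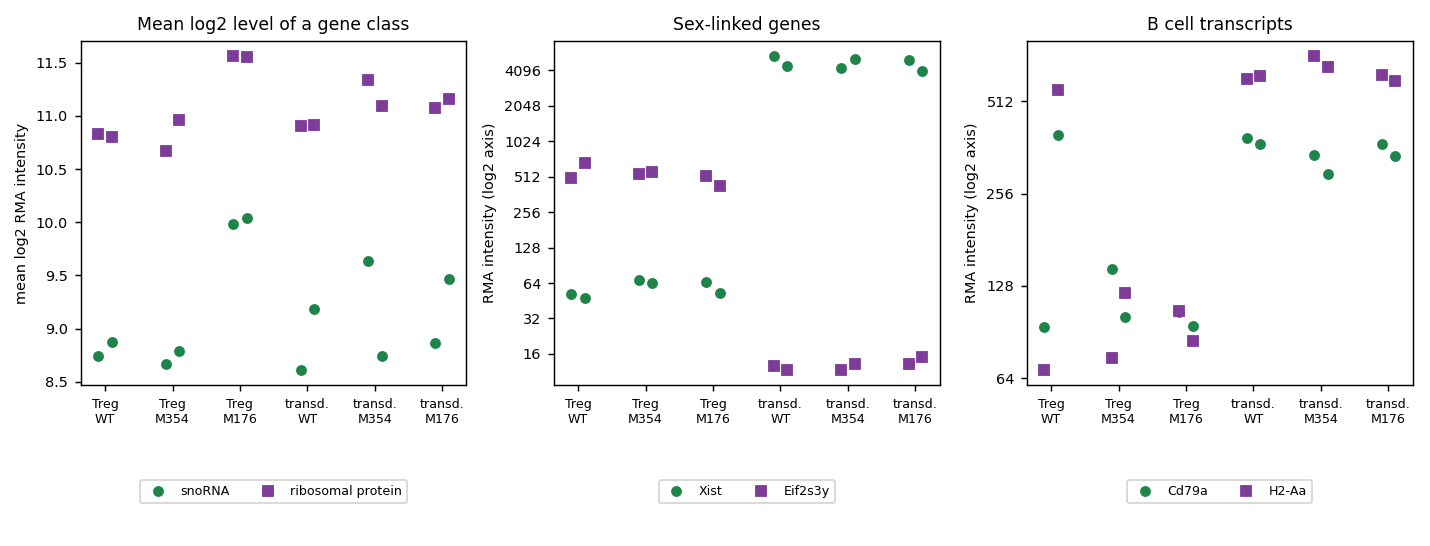
Values per array: mean log2 level of 36 snoRNA and scaRNA genes and 56 ribosomal protein genes, and intensities (log axes) of Xist and Eif2s3y and of the B cell genes Cd79a and H2-Aa, 1 point per array. The snoRNA mean was 9.98 and 10.04 in M176 Tregs, Xist lay between 4015 and 5367 in transduced cells and between 47.6 and 68.5 in Tregs, and H2-Aa was 557 in WT Treg replicate 2 against 68.2 in replicate 1.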

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

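The tests of the share of Foxp3-expressing cells, of the glycolysis genes and of B cell RNA, and the snoRNA level as a covariate, were chosen only after the result was seen. All results listed here drew attention for the same reason: the effect of an allele on them in Tregs differed from its effect in transduced cells by limma's test of the difference or, for lists, by camera on that difference. All differences are the log2 change in Tregs minus the log2 change in transduced cells.

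For M354, 96 genes differed. Upward differences were 2.59 for Cxcl10, 2.50 for Ak4, 2.08 for Srsy, 2.04 for Egln3, 2.02 for Prelid2, 1.92 for Plod2, 1.83 for Bhlhe40, 1.80 for Ndrg1, 1.78 for Cxcr6 and 1.77 for Vegfa. Downward differences were -1.46 for Mir15b, -1.38 for Cd7, -1.34 for Ly6a2, -1.25 for Ifitm3, -1.23 for Klrd1, -1.22 for Sidt1, -1.20 for Slc28a2b, -1.12 for Slc35d1, -1.12 for Mid1 and -1.09 for Prkd3. Some of these calls were lost with 1 array left out. The highest adjusted p was then 0.315 for Mir15b and 0.273 for Ifitm3, both without M354 Treg replicate 1. It was 0.198 for Klrd1 without M354-transduced replicate 1 and 0.175 for Slc35d1 without M354-transduced replicate 2. For Prkd3 it was 0.109 without WT Treg replicate 2, for Srsy 0.0878 and for Mid1 0.0512 without M354 Treg replicate 2. Of 12 arrays, leaving out 9 ended the call of Mir15b, 9 that of Slc35d1, 8 that of Klrd1, 6 that of Ifitm3, 5 that of Prkd3, 3 that of Srsy and 1 that of Mid1. Srsy is Y-linked and the transduced arrays express no Y-linked genes (Srsy at 27.1 with WT and 25.2 with M354), so its difference restates the change in Tregs. In Tregs Klrd1 (31.6 with WT, 28.2 with M354) and Ak4 lay near background, so their differences restate the changes in transduced cells. Plod2 in WT Tregs (28.5) was also near background, so the size of its difference is open. Lists with an upward mean difference were glycolysis at 0.771, Th2 at 0.517, Th17 at 0.432, genes high in Tregs at 0.405, effector Tregs at 0.402, IL-2 and STAT5 targets at 0.289 and the early T cell receptor response at 0.199. Resting Treg genes differed by -0.399. With an estimated correlation only glycolysis was still called among these 8 lists.

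For M176, 488 genes differed. Upward differences were 2.70 for Hspa1a, 2.35 for Ak4, 2.18 for Chil5, 2.14 for Snord61, 2.05 for Srsy, 2.04 for Ciart, 1.99 for Rps21, 1.98 for Rpl24, 1.97 for Prelid2 and 1.97 for Fos. In transduced cells Srsy (27.1 with WT, 26.6 with M176) and Snord61 (25.8 and 21.0) lay near background, so their differences restate the changes in Tregs. In Tregs Ak4 lay near background, and its difference restates the fall in transduced cells. Downward differences were -2.52 for Gzmb, -2.44 for Ccna2, -2.36 for Klrg1, -1.90 for Ccr2, -1.89 for Mki67, -1.84 for E2f8, -1.78 for Ccnb2, -1.78 for Ctsg, -1.77 for Ccr6 and -1.72 for Kif11. Lists with an upward mean difference were glycolysis at 0.822, heat shock at 0.812, interferon response at 0.434, genes low in Tregs at 0.337, cholesterol synthesis at 0.330 and the early T cell receptor response at 0.328. Downward mean differences were -0.770 for proliferation, -0.670 for B cell markers, -0.616 for effector Tregs, -0.396 for Th2 and -0.268 for genes high in Tregs. None of these 11 lists was called with an estimated correlation.

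In M176 Tregs, proliferation and effector genes fell while snoRNA and ribosomal protein genes rose, which could come from a different recovery of RNA on these arrays, from fewer Foxp3-expressing cells in the CD25-high sort, or from the allele. With the snoRNA level as a covariate the mean change of the effector list was -0.821 (SE 0.156), against -0.851 (SE 0.0838) without it. For proliferation genes it was -0.788 (SE 0.271) against -0.849 (SE 0.147), more than 2 SE from 0, although the stricter bound set beforehand was not met. The covariate slope rests mainly on transduced arrays, whose replicates differed more in snoRNA level than Treg replicates. That level was 9.64 and 8.75 in M354-transduced cells, against 9.98 and 10.04 in M176 Tregs. These means argue against RNA recovery as the whole cause only if it acts in Tregs as in transduced cells. A recovery effect of another size in Tregs, or a partial one, stays open. Across genes, slopes on the snoRNA level within the transduced groups correlated with the M176 changes in Tregs at 0.267, between the bounds set beforehand for and against recovery (0.0851 with the M354 changes), which leaves the snoRNA and ribosomal rises open. The 21 genes high in Tregs outside the effector list, Foxp3 itself left out, had a median change of -0.21 (SE 0.112, 16 lower and 5 higher) against -0.73 (SE 0.13) for Foxp3, so a lower share of Foxp3-expressing cells and the allele cannot be told apart.

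Glycolysis genes fell with both mutant alleles in transduced cells, by means of -0.818 and -0.890, which could reflect a different recovery of RNA, a difference between the WT cultures and the others, or an allele effect. With the snoRNA level as a covariate the means were -0.806 (SE 0.0834) with M354 and -0.878 (SE 0.0826) with M176, which argues against recovery as the whole cause. In Tregs the list mean was -0.0474 (SE 0.0737) with M354 and -0.068 (SE 0.0737) with M176, so a fall of the size seen in transduced cells was absent. Adjusted over the list alone, 3 genes rose and 3 fell with M354, and 2 and 2 with M176, Slc2a3 falling with both. All 14 genes were lower in WT Tregs than in WT-transduced cells (mean -1.845). An allele effect on the higher expression in culture might not show in Tregs, so these means do not decide on an effect common to both systems. The M354- and M176-transduced cells differed from each other by 0.0714 (SE 0.0737), as a difference of the WT cultures or an allele effect would give. Each allele's cultures form 1 group, so a difference of the WT cultures and an allele effect in culture cannot be told apart.

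WT Treg replicate 2 held more B cell transcript than replicate 1, with a median log2 gap of 0.728 over 13 markers, above the upper bound of 0.122 from 10000 random lists of matched level. Of the 13 markers 11 were higher, with Cd74 at 1070 against 536 and Cd79b at 902 against 654, while Cd72 (371 against 399) and Ighm (134 against 139) were not. B cells left in that sample are a candidate source, although the CD4+ CD25-high sort would remove them. Because Cd72 and Ighm did not rise, B cell RNA and a different state of the sorted cells cannot be told apart, and no biological difference between the WT replicates is named in the labels.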

How the results depend on the processing

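The snoRNA covariate, the test without small RNA and ribosomal protein genes, and the crossed block were chosen only after the result was seen. Counts of called genes that moved by more than 1.5 times were as follows, and apart from the filter, which tests fewer genes, and the thresholds, which change the calls by construction, the cause was not tested.

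Quantile normalization gave 277 genes for M354 against WT Tregs and 1 for M354- against M176-transduced cells. Testing every probe set gave 307 and 1 for the same comparisons. The filter at percentile 75 gave 1572 genes for M354 against M176 Tregs, 76 and 26 for M354 and M176 against WT in transduced cells, 0 between the mutants there, 54 for the system difference of M354 and 1338 for WT Tregs against WT-transduced cells. For M176 Tregs the snoRNA covariate, which widens the SE, gave 363 against WT (320 among the 2207) and 570 against M354 (513 shared). It gave 170 for the system difference of M176 (146 shared) and 12 between the transduced mutants. Without small RNA and ribosomal protein genes that last count was 12, with trended and robust variances 12 and with array weights 11. An adjusted p under 0.10 gave 272 and 185 genes for M354 against WT in Tregs and transduced cells, 16 between the transduced mutants and 894 for the system difference of M176. A change of at least 1.5-fold left 1130 for M176 against WT Tregs, 1385 for M354 against M176 Tregs and 1398 for WT Tregs against WT-transduced cells. Cyclic loess normalization, no filter, the fit per system and the mean over probe sets kept every count within 1.5 times.

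With any 1 array left out, counts lay between 73 and 212 for M354 and 916 and 2386 for M176 against WT Tregs, 1343 and 2879 for M354 against M176 Tregs, 42 and 140 for M354 and 23 and 53 for M176 against WT in transduced cells, and 1 and 18 between the transduced mutants. For the system differences they lay between 57 and 90 for M354 and 148 and 540 for M176, and for WT Tregs against WT-transduced cells between 1506 and 2767. Called lists numbered 78 to 89. An arm left with 1 array was assumed to vary like the others. Correlations of allele effects lay between -0.0685 and 0.191 in Tregs, the lowest without M354 Treg replicate 2, between 0.44 and 0.778 in transduced cells, and across systems between 0.0112 and 0.323 for M354 and 0.121 and 0.428 for M176. For M176 across systems r was also 0.229 with no filter and 0.428 with the filter at percentile 75.

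The replicate number as a block gave 114 and 1844 genes for M354 and M176 against WT Tregs, 2361 between them, 99, 43 and 7 for the same comparisons in transduced cells, 78 and 350 for the system differences and 2333 for WT Tregs against WT-transduced cells, and 85 lists. Arrays with the same number deviated from their group means with correlations between -0.55 and 0.08 across genes, so equal numbers do not pair the samples. In M354-transduced cells the deviations ran against those of equal number in WT (-0.55) and M176 (-0.33), so arrays of opposite number deviated alike there. The tests and the simulated correlation treated all arrays as independent. The crossed block gave 140, 52 and 10 genes in the transduced comparisons.

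Of 83 calls of lists 5 held with an estimated correlation and 56 with fry (67 lists called by fry in all). Without a filter 8 calls were lost, those of genes high in Tregs, Th1 and Th17 in M354 Tregs (adjusted p = 0.294, 0.0651 and 0.0671) among them, and with quantile normalization 11. The snoRNA covariate ended 6, with cholesterol synthesis in M176 against WT Tregs at 0.0836 and in M354 against M176 Tregs at 0.0868. The call of B cell markers in M354 Tregs ranged from adjusted p = 1.96e-17 to 0.216 with 1 array left out and turned in direction without WT Treg replicate 2 (0.0739). Of 463 values of single genes, 437 kept direction and call with quantile normalization, 443 of 462 with cyclic loess and 386 with the snoRNA covariate, which reversed 3: Snora73a in M176 against WT Tregs (-0.58), and Vaultrc5 (1.02) and Snora69 (0.096) in M354 against M176 Tregs, all snoRNA or small RNA genes and in part the covariate itself.

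A gene was tested if it passed the median on 2 of the 12 arrays. Tested genes can lie near background, as Gzmb did in M176 Tregs, and the size of their changes is then open. At 2 arrays per group simulated changes of 1.5-fold were recovered in 61.6% to 65.8% of cases against WT and 16.1% to 21.3% for system differences.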

Other observations

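The description of Flicr and Srsy was chosen after their values were seen. Flicr, a long noncoding RNA transcribed beside Foxp3, was measured in Tregs at 376.9 ± 29.8 with WT, 503.7 ± 26.1 with M176 and 271.3 ± 4.43 with M354 Foxp3 (SD, n = 2 each). It rose in M176 Tregs against WT (log2 0.42, SE 0.13, limma adjusted p = 0.0305), where Foxp3 fell, did not pass with M354 (log2 -0.47, adjusted p = 0.0911), and was lower in M354 than in M176 Tregs (log2 -0.89, adjusted p = 0.000121). The transduced arrays held between 65.8 and 81.8.

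The Y-linked transcript Srsy rose in both mutant Treg groups, by 1.97 with M354 and 2.02 with M176, from 43.05 ± 17.2 in WT Tregs (SD, n = 2), a level near its background on the transduced arrays (25.2 to 27.1), so the size of the rise is not determined. Uty and Kdm5d, also Y-linked, lay between 491 and 656 and between 315 and 445 on all 6 Treg arrays and between 16.6 and 24.7 and between 20.1 and 30.4 on the transduced arrays.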
